A study of Cricetulus griseus with 16 samples.

How the data were processed

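RNA from CHO-K1 cells, a line derived from Chinese hamster ovary, was measured on 16 two-colour Agilent arrays of a custom Chinese hamster design. Each array carried RNA of 1 sample in one dye and a reference pool of RNA from different Chinese hamster ovary lines in the other. The labels gave 2 conditions, serum and serum-free, with 4 biological replicates each and 2 arrays per replicate. On technical replicate 1 the sample was labelled with Cy3, and on technical replicate 2 with Cy5. Groups, replicate numbers and dyes were taken from the labels. The labels repeated each culture name in 2 replicates of a condition (passage 17 or 18 in serum, c1 or c2 in serum-free), so the 4 replicates of a condition may not be 4 separate cultures, and the p-values then measure only the spread between these samples.

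The deposited scanner files held the median spot intensity and the median local background intensity of each channel, on a linear scale and not yet background-subtracted, as Agilent Feature Extraction 11.5.1.1 wrote them per the file headers. They also held Feature Extraction's own log10 ratio of red (Cy5) over green (Cy3), background-subtracted and dye-normalized per the file headers, and its 0 or 1 marks per spot. The authors' deposited value table gave a log2 ratio per spot. Set against each array's scanner values over spots well above background in both channels, its columns correlated at 0.98 to 1.00 with the log2 ratio of red over green, with slopes of 0.94 to 1.00. The slopes fix the scale as log2, and their sign shows that the dye swap had not been turned. The column medians lay between 0.012 and 0.028, and whether the authors centred them is unknown. The labels and headers used here did not state how the table was made.

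Spots were processed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with an offset of 50, ratios were normalized by loess within each array with control spots at weight 0, and spots that Feature Extraction marked as non-uniform or population outliers were then left out. The plan named the mean spot signals, but the files used here held medians, which were used in their place. Ratios were turned to sample over pool on the log2 scale, the spots of a sequence were averaged, and the 2 dye-swapped arrays of a replicate were averaged to 1 value. A sequence was tested if it was well above background in the sample's channel on both arrays of all 4 replicates of at least 1 condition. A sequence counted as well above background on an array when more than 50% of its spots carried Feature Extraction's mark. This kept 7768 of 20940 sequences. Of the 20940, 20924 had 2 spots per array and 16 had more, and no spot was saturated on any of the 16 arrays. Each sequence had 1 probe, so no choice between probes arose.

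The conditions were compared with limma's lmFit and eBayes over 8 replicate values, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Late and early sampling, their difference between the conditions, and the culture labels within each condition were compared by contrasts of cell means over the same 8 replicates. All tests, samples and alternatives were fixed before the data were examined, except those named as chosen after seeing the data. The plan's rule for named genes took sequences past the threshold whose 4 serum values all lay on one side of the 4 serum-free values, with the same sign in both dye orientations, in order of log2 difference. The rule also asked for a gene symbol. The files pair no gene names with the sequence identifiers, and 0 of the 20940 identifiers matched the reference gene table of the CriGri-PICRH-1.0 assembly (32251 genes). The symbol requirement was therefore dropped and the 2 highest and 2 lowest sequences were named by identifier. For the same reason the 34 gene lists written beforehand, including the cell type markers, had 0 measured members by name and were not tested.

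A step outside the plan was examined after both call counts had been seen. Across the 16 arrays, 78 spots had a local background over 2 times their array's median in either channel, up to 79683 in red and 82330 in green against array medians of 65 to 69 and 26 to 33. With these spots kept, as planned, the lowest correlation of an array's ratios with the mean of the other arrays of its condition and dye was 0.28, against 0.90 with them left out. Leaving the spots out before background correction was added as an alternative for every comparison. The planned processing, with every spot kept, remained the reported one, and values with the 78 spots left out are given beside the main counts.

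The functions were tested on simulated data of 7768 sequences with the measured spreads and 200 changed sequences. For serum against serum-free, 93% of changes of 0.5 on the log2 scale and 98% of changes of 1 were recovered, with 13 false calls. For late against early these shares were 90% and 97%, for their difference between the conditions 24% and 84%, for passage 18 against 17 78% and 95%, and for c1 against c2 73% and 98%. From simulated spot intensities passed through background correction and loess, a change of 1 in serum against serum-free was estimated at a median of 0.77, smaller than simulated. The simulated spots had each array's median background throughout, with no aberrant spots. Noise between replicates was drawn independently, with the same spread in each. Recovery and false calls on the real arrays with all spots kept may therefore differ.

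For a sequence well above background on no array of a condition, a bound on the fold was computed. It set the brighter condition's mean against the dimmer condition's mean of, per array, the higher of its own signal and the lowest signal among sequences well above background, from channel values after loess and Aquantile. Other alternatives were Feature Extraction's ratio, no background subtraction, median centring, Aquantile scaling, the authors' value table, other filters, 1 dye orientation alone, other variance models, blocks and covariates, and each replicate left out. The precision of the arrays is limited by their number. All 4 slides were scanned on the same day. Each slide held 1 condition and 1 sampling phase, so phase and slide cannot be told apart within a condition.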

Results

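The series measured transcripts of CHO-K1 cells, a Chinese hamster ovary line used to produce recombinant proteins, in 2 culture states. Serum cultures grew in DMEM/Ham's F12 with 5% fetal calf serum and 4 mM glutamine, at passage 17 or 18, and RNA was taken on day 3. Serum-free cultures had been adapted to suspension in CD CHO medium with 8 mM glutamine and 0.2% anti-clumping agent, at passage 21, and RNA was taken on day 2. Medium, growth in suspension, passage and day therefore all differed between the conditions, which had 4 replicates each. Every replicate was hybridised on 2 arrays, with dyes swapped, against a pool of RNA from different Chinese hamster ovary lines. The median spot intensity was 68 to 109 in green over a local background of 26 to 33, and 73 to 82 in red over a background of 65 to 69. Between 12419 and 14232 of 20940 sequences were well above background in the sample's channel when the sample was in Cy3, and between 7320 and 10574 when it was in Cy5.

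Serum and serum-free cells were compared to find transcripts that differed between the culture states. With the planned processing, the sequence with the largest difference, gi-346716115.1, was 17.1-fold lower in serum, with a log2 difference of -4.09 (SE 0.22, limma adjusted p = 4.58e-05). Its log2 ratio to the pool was -3.13 ± 0.48 (SD, n = 4) in serum and 0.97 ± 0.24 (SD, n = 4) in serum-free cells, and it was well above background on all 16 arrays. The sequence gi-354484896.1 was 8.10-fold lower in serum, at a log2 ratio of -1.53 ± 0.57 against 1.48 ± 0.19 (SD, n = 4 each), a difference of -3.02 (SE 0.25, limma adjusted p = 0.00016). It was well above background on 8 of 8 serum-free arrays but on 4 of 8 serum arrays.

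In the other direction, gi-354502588.1 was 4.38-fold higher in serum, with a log2 ratio to the pool of 1.89 ± 0.62 against -0.24 ± 0.04 (SD, n = 4 each). The log2 difference was 2.13 (SE 0.26, limma adjusted p = 0.00089), and 4 of 8 serum-free arrays measured it well above background. The sequence gi-354478977.1 was 3.53-fold higher in serum, by 1.82 (SE 0.37, limma adjusted p = 0.0099), at -0.65 ± 0.23 in serum and -2.47 ± 0.86 in serum-free cells (SD, n = 4 each). That size rested in part on serum-free replicate 2, whose ratio was -3.76 where the other serum-free replicates lay between -2.10 and -2.02. Without that replicate the difference was 1.39 (limma adjusted p = 4.05e-05). For these 4 sequences the 2 dye orientations gave the same direction, as the rule for naming them required. With 78 spots of aberrant local background left out, the log2 differences were -4.55 for gi-346716115.1, -3.54 for gi-354484896.1, 2.56 for gi-354502588.1 and 1.31 for gi-354478977.1. Another sequence then ranked second among those higher in serum, at 2.13 (limma adjusted p = 3.28e-08). The sizes of the named sequences depended on the background handling, and not only for those near background in one condition. Feature Extraction's ratio gave -6.55 for gi-354484896.1 and 5.26 for gi-354502588.1, and the authors' value table -5.62 and 4.14. In both, gi-354484896.1 rather than gi-346716115.1 (-5.09 and -4.99) had the larger difference. The files pair no gene names with these identifiers, so the genes are not named.

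**Figure D1:**
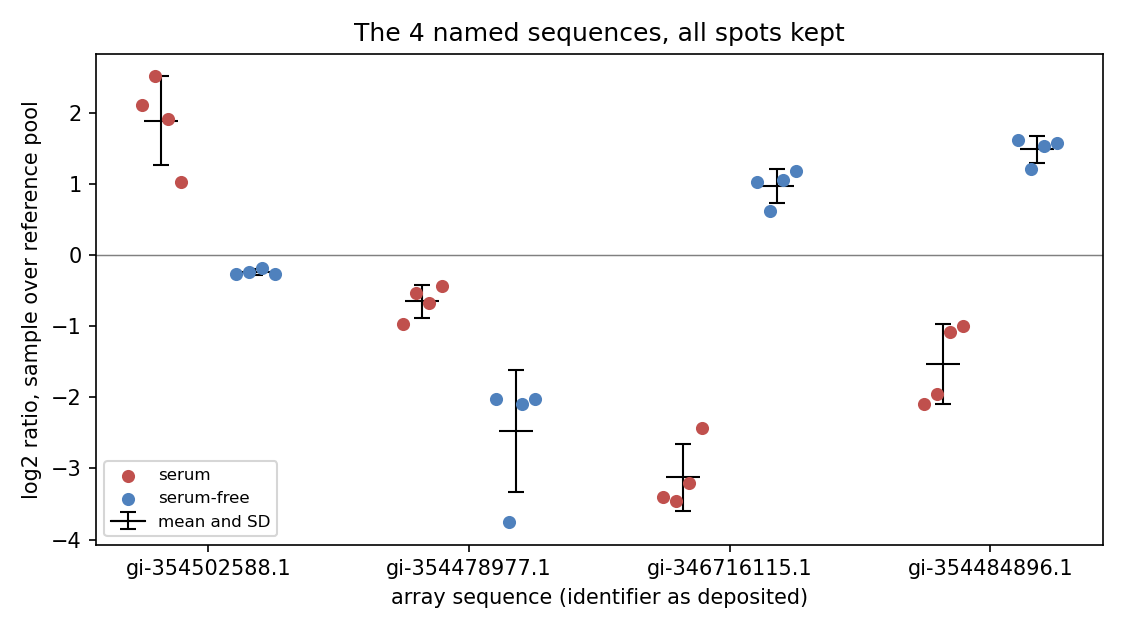
Log2 ratio of sample over reference pool (vertical axis) for the 4 named sequences, 2 higher and 2 lower in serum (horizontal axis). Points are the 4 replicates of each condition, each the mean of 2 dye-swapped arrays, with all spots kept, and black marks are the mean and SD. For gi-346716115.1 the serum values lie between -3.46 and -2.43 and the serum-free values between 0.62 and 1.18.

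Of 7768 sequences tested, 1430 (18.4%) passed the threshold, 630 higher and 800 lower in serum (limma, adjusted p under 0.05). Most differences were small with the planned processing, which also shrank simulated changes, a log2 change of 1 coming out at 0.77. Of the 1430, 528 higher and 647 lower sequences differed by less than 1.5-fold, and the median absolute log2 difference was 0.32. At least a 2-fold difference was seen for 74, 19 higher and 55 lower in serum, and 1 higher and 5 lower sequences reached 4-fold. The 4 values of one condition lay entirely to one side of the other condition's in 1354 of the 1430. That count is largely built in, since the 1430 were selected by the same difference. Over all tested sequences the share was 23.4%, where chance gives 2.86% if the 8 replicates are independent. The repeated culture labels leave that independence in doubt. The direction was the same in both dye orientations for 1422, which is largely built in, since the mean of those orientations was tested. Calls were more frequent among bright sequences, at 26.3% of the 2590 brightest sequences and 10.6% of the 2589 dimmest by mean log2 intensity. With the 78 spots left out these shares were 45.3% and 22.8%, and 3 higher and 9 lower sequences reached 4-fold. With all spots kept, calls of at least 2-fold numbered 48 among the brightest and 3 among the dimmest. The median SE of the tested sequences was 0.071 and 0.048. How much the processing shrank changes was not examined by brightness, so it may contribute to this trend.

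The number of calls depended on the processing. When the 78 spots with an aberrant local background were left out, a choice made after seeing the data and after both counts were known, 2756 sequences passed, 1238 higher and 1518 lower, and 97 were at least 2-fold. Of the 1430 sequences, 1425 were among these 2756, and 0 of the 1430 changed direction. With median centring in place of loess and all spots kept, 158 passed, 18 higher and 140 lower, and 182 of the 1430 had the opposite sign without passing. Feature Extraction's own ratios gave 3151, with 1611 higher and 1540 lower, so that more were higher than lower.

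Some sequences were well above background in only one condition. In the sample's channel, 9 were so on all 8 serum-free arrays and on no serum array, and all 9 passed the test as lower in serum (highest limma adjusted p = 0.0105). The reverse held for 3 sequences, and all 3 passed the test as higher in serum (highest limma adjusted p = 0.0127). Passing and direction are largely built in, since the marks that picked these sequences come from the same arrays. The fold of the ratios to the pool was small, 1.23 to 1.79 for the 9 and 1.30 to 1.60 for the 3. The marks therefore do not show that a transcript was absent from a condition. No bound on the fold is given for these 12, because the bounds from single channels exceeded the fold of the ratios for 9 of 9 and 2 of 3. Another 6750 sequences were well above background on all 16 arrays, and 5800 on no array in either channel.

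**Figure D2:**
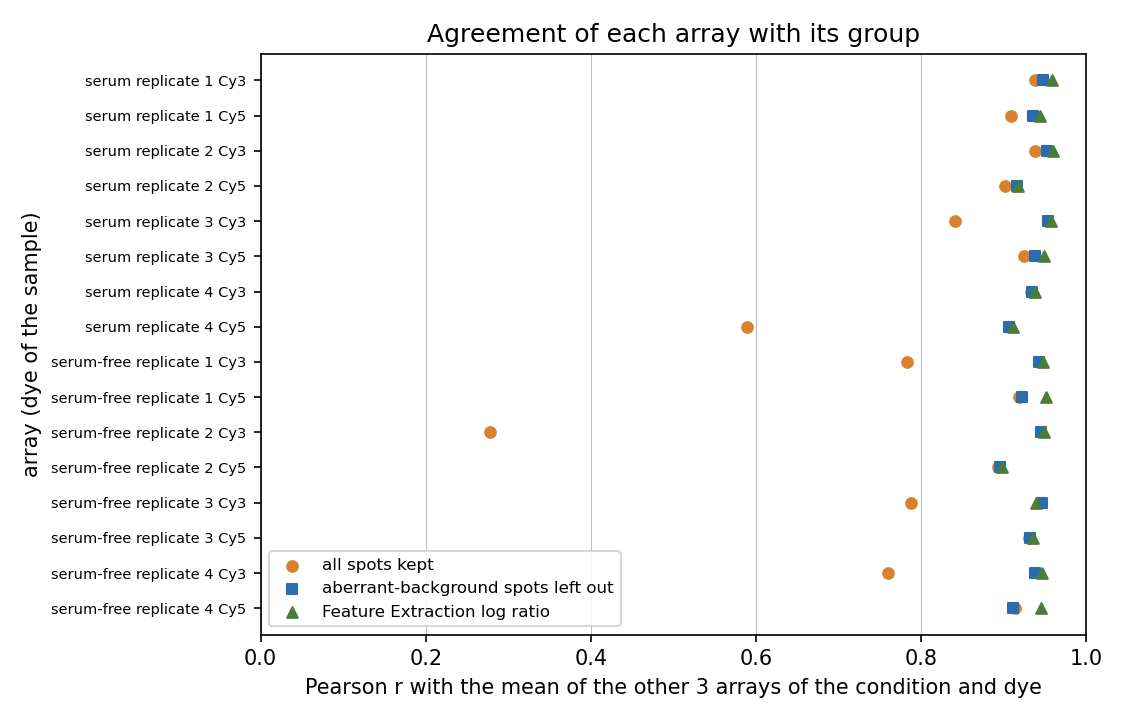
Pearson correlation across 7768 sequences (horizontal axis) of each of the 16 arrays (vertical axis, named by condition, replicate and dye of the sample) with the mean of the other 3 arrays of its condition and dye. With all spots kept, the array of serum-free replicate 2 in Cy3 stands at 0.28 and that of serum replicate 4 in Cy5 at 0.59, whereas with aberrant-background spots left out the lowest value is 0.90.

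Against the pool, 4746 of the 7768 tested sequences differed in serum cells and 4214 in serum-free cells (limma, adjusted p under 0.05), and 3219 differed in both. Of those 3219, 2954 lay on the same side of the pool in both conditions. At least 2-fold differences from the pool numbered 139 in serum and 62 in serum-free cells. Among the 74 sequences that differed at least 2-fold between the conditions, serum cells were farther from the pool for 60 and serum-free cells for 14. All of these counts share the same pool, and the numbers of the 2 conditions were not tested against each other. With the 78 spots left out, 5574 sequences differed from the pool in serum and 5376 in serum-free cells.

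The first principal component of the replicate values separated the conditions and held 52.9% of the variance. Replicate values correlated across sequences at 0.85 to 0.95 within serum, 0.49 to 0.95 within serum-free and 0.20 to 0.69 between the conditions. The lower values within serum-free involve replicate 2, whose 2 dye-swapped arrays correlated at -0.04 with all spots kept. With the 78 spots left out, correlations were 0.91 to 0.97 within serum, 0.91 to 0.96 within serum-free and 0.62 to 0.69 between the conditions, and the first component held 77.1%. Sequences are not independent replicates.

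Late and early sampling within the day were compared across both conditions, 4 replicates against 4. No sequence passed, with 439 at an unadjusted p under 0.05 where 388.4 are expected by chance (limma), and Feature Extraction's ratios also gave 0 calls. The smallest adjusted p was 0.45. Leaving out serum-free replicate 1 gave 294 calls, which left the late serum-free samples with replicate 2 alone, assumed to vary like the others. With the 78 spots left out as well, the same fit gave 0. The late minus early difference was also compared between the conditions, and 0 sequences passed, with 890 at an unadjusted p under 0.05 (limma). Leaving out the 78 spots, 0 passed and 274 had an unadjusted p under 0.05, fewer than the 388.4 expected. Feature Extraction's ratios gave 0 and 371. Without serum-free replicate 1 the count was 517, or 0 with the 78 spots left out. Each phase of a condition lay on its own slide, so these contrasts measure phase or slide.

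Culture labels within a condition were compared on 2 replicates each. Each slide held both labels of its condition, so differences between slides or phases enter the error of these fits. A lack of calls therefore does not show that the cultures were alike. For passage 18 against passage 17 in serum, 0 sequences passed and 353 had an unadjusted p under 0.05 (limma). With the 78 spots left out 0 passed, the smallest adjusted p was 0.071 and 864 had an unadjusted p under 0.05, where 388.4 are expected by chance. Feature Extraction's ratios gave 1 call and 1001 at an unadjusted p under 0.05. With all spots kept and phase within each condition as a covariate, 0 passed and 415 had an unadjusted p under 0.05 (limma). For c1 against c2 in serum-free cells with that covariate, 0 passed and 182 had an unadjusted p under 0.05 (limma). Without the covariate 0 passed and 74 had an unadjusted p under 0.05 (limma), fewer than the 388.4 expected, and Feature Extraction's ratios gave 0 calls. Without serum-free replicate 3, which left c2 to replicate 2 alone, 306 passed, and 0 did so with the 78 spots left out.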

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

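The tests of array agreement were chosen after the result was seen. The tests of other splits and of the pool's channel were fixed before their results.

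On the array level, 3 arrays stood apart from the other arrays of their condition and dye when all spots were kept. Serum-free replicate 2 in Cy3 correlated at 0.277 with the mean of its group, where the other 3 arrays were at 0.76 to 0.788. Serum replicate 4 in Cy5 was at 0.59 against 0.902 to 0.925, and serum replicate 3 in Cy3 at 0.841 against 0.933 to 0.939. In the same way, serum-free replicate 2 lay at -3.76 for gi-354478977.1, where the others lay at -2.10 to -2.02. These 4 were the values far from the rest among 22 groups of 4 examined, by Dixon's test at its 95% critical value, which chance passes in about 1 in 20 groups. The array values of one group are not independent, since each mean contains the other arrays.

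Fewer sequences were called with all spots kept than with the 78 spots left out, 1430 against 2756. Poor hybridisation of single arrays is argued against: in Feature Extraction's own ratios the lowest correlation of an array with its group was 0.899. Leaving out only the 78 spots brought the lowest correlation from 0.277 to 0.896, as a few extreme local backgrounds distorting the background model of some arrays would give. The number of such spots alone did not set the change. Serum-free replicate 2 in Cy3 had 21 and moved from 0.277 to 0.946, but serum-free replicate 1 in Cy5 had 16 and moved from 0.919 to 0.922. Both tests were chosen after these values were seen, so the distortion is a hypothesis. No biological explanation was tested.

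The difference between serum and serum-free cells was set against other groupings of the 8 replicates. Of 35 splits, 1 gave as many as 1430 calls, the real one, and the highest of the others was 0. A share of 1 in 35 is the smallest possible. It makes chance unlikely for that count if the 8 replicates are independent, which the repeated culture labels leave in doubt. With the 4 culture labels or the 4 slides as units there are only 3 splits, too few for a share under 0.05. For the 74 sequences at least 2-fold apart, 1 of 35 splits gave as many and the highest of the others was 0. That result adds nothing to the first, since a split with 0 calls can hold no call of at least 2-fold. Drift of the pool's channel between slides is argued against as the whole source. Over the 1430 sequences the slope of minus the pool's difference on the ratio's difference was -0.057 (95% interval -0.065 to -0.048). A drift carrying the ratios would give 0.5 or more. The interval measures scatter across sequences, which are not independent, and not the uncertainty over the 4 slides. Medium, suspension growth, passage, day and slide remain open, because the design gives each condition its own.

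For late against early sampling, the 18 splits within the conditions are too few for a share under 0.05. The real split gave 0 calls, the highest of the others was 0, and all 18 gave as many as the real one.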

How the results depend on the processing

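Leaving out aberrant spots or the 2 arrays of lowest agreement was chosen after seeing the data, the other settings beforehand. For serum against serum-free, the planned fit called 1430 sequences and 74 at least 2-fold. Counts moved by over 1.5 times with Feature Extraction's ratio (3151 and 282), with the authors' value table (2727 and 228) and with median centring (158 and 123). No background subtraction gave 2798. Only Cy3 arrays gave 529, only Cy5 arrays 554, and treat at a log2 difference of 1 gave 3 (54 with aberrant spots left out). Averaging the samples of a culture label gave 945, on 4 values instead of 8. Otherwise the cause was not tested. With aberrant spots left out the total was 2756, or 2755 at a threshold of 3 times the median, 2278 on Cy3 arrays alone and 1503 on Cy5 arrays alone. Leaving out serum replicates 1 to 4 as well gave 2544, 2395, 2549 and 2849, and serum-free replicates 1 to 4 gave 2311, 2474, 2473 and 2432. Adding median centring to the left-out spots gave 999, 211 higher and 788 lower, and 131 at least 2-fold. Without each replicate in turn, the planned fit gave 954 to 1630 and 66 to 84 at least 2-fold. Without the 2 arrays of lowest agreement it gave 1656 and 96.

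The replicate block gave 934 calls and 71 at least 2-fold. Deviations of samples with the same number correlated at -0.02, 0.06, -0.07 and 0.03 for numbers 1 to 4, and at 0.08, 0.30, 0.25 and -0.01 with aberrant spots left out. In neither case was every pair over 0.1, so the numbers were not taken to pair the samples. Best matches were to the own number for serum replicate 2 alone, and with aberrant spots left out for serum replicates 2 and 3 and serum-free replicates 1, 2 and 3. A random slide block gave 1299, with an estimated correlation of 0.07 between samples of a block. A culture block gave 1793, with an estimated correlation of -0.17. The negative value treats samples of a culture label as less alike than others. The higher count therefore does not show that the result withstands shared cultures.

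The 4 named sequences kept their direction in every setting that measured them, but not their size. The values from Feature Extraction's ratio and the authors' value table are given with the sequences. Only gi-354478977.1 fell short of the threshold, at 0.80 with median centring (adjusted p = 0.191) and 2.18 on Cy3 arrays alone (adjusted p = 0.13), in a range of adjusted p down to 8.60e-08 with the authors' value table. Without each replicate in turn, late against early gave 0 to 294 calls, its difference between the conditions 0 to 517, c1 against c2 0 to 306 and passage 18 against 17 0 throughout. Late against early gave 1 without serum-free replicate 2. With aberrant spots left out these ranges were 0 to 5, 0 to 1, 0 throughout and 0 to 1. Passage 18 against 17 gave 1 with Feature Extraction's ratio. Gene list settings were not run, as no identifier had a name. A mean over probes (1 per sequence) and removal of saturated spots (none) were not run. The filter asks for signal in both dyes, so the dimmer Cy5 arrays limited which sequences were tested.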

Other observations

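Leaving out the 78 spots, the contrast within serum and the comparison of the dye orientations were chosen after seeing the data. The probe for enhanced green fluorescent protein, egfp.1, was well above background in 0 of 64 spot channels. Of 30240 spot channels of the linker probes on the array, 68 (0.225%) were well above background, against 9 of 4896 (0.184%) for negative control spots (Fisher's exact test, one-sided p = 0.355). These are 945 and 153 spots read on every array in both channels, so the spot channels are not independent as the test assumes. Only 2 sequences were well above background in the pool's channel on all 16 arrays and in the sample's channel on none. Taking the sequences well above background on all arrays of one condition and none of the other, 12 in all, the highest count in any of the other splits of the 8 replicates was 0.

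With the 78 spots left out, log ratios to the pool spread more widely in serum than in serum-free cells. The SD across the 7768 tested sequences was 0.391 ± 0.026 in serum and 0.321 ± 0.0074 in serum-free replicates (SD, n = 4 each, exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 can give). With all spots kept these were 0.352 ± 0.059 and 0.320 ± 0.034 (SD, n = 4 each, exact permutation p = 0.343, two-sided), so the pattern depends on that step. On Cy3 arrays the mean SD was then lower in serum, 0.391 against 0.443, and on Cy5 arrays higher, 0.395 against 0.349. Over the 6750 sequences well above background on all 16 arrays the difference was 0.065, and every serum replicate lay above every serum-free one. These sequences are most of the 7768, and the mark does not equalise signal over background between the conditions. The test therefore cannot decide whether a difference in signal over background is the source. A labelling difference confined to 1 dye orientation is argued against as the whole source. The smaller of the differences in the 2 dye orientations was 0.052, and the Cy3 difference minus the Cy5 difference was -0.00041 (SE 0.015, 4 replicates each), where a difference in 1 orientation alone needs 0.105. On Cy5 arrays the conditions overlapped, with a lowest serum value of 0.377 and a highest serum-free value of 0.400, so the separation asked for beforehand was not met. With the 78 spots left out, the 2 dye-swapped arrays of a replicate correlated at 0.677 ± 0.054 in serum and 0.467 ± 0.044 in serum-free cells (SD, n = 4 each, exact permutation p = 0.0286, two-sided). With all spots kept the correlations were 0.591 ± 0.137 and 0.328 ± 0.251 (SD, n = 4 each, exact permutation p = 0.114, two-sided). Averaging arrays that agree less narrows replicate ratios, so the replicate difference of 0.070 may partly reflect this. Dye effects of single sequences in both orientations are not covered by these tests. A pool closer in makeup to serum-free cells may also give the wider spread in serum, and was not tested.

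Within serum alone, late against early sampling gave 9 sequences past the threshold with all spots kept (limma, 1006 at an unadjusted p under 0.05), and 0 with the 78 spots left out (185 at an unadjusted p under 0.05). Within serum-free cells it gave 0 in both settings (259 and 524 at an unadjusted p under 0.05).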
